A study of Mus musculus with 8 samples.

How the data were processed

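RNA of cultured mouse hippocampal neurons was measured at 4 times of exposure to 50 µM bicuculline, with 2 biological replicates per time. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, labelled with biotin and hybridised to Affymetrix Mouse Gene ST 1.0 arrays, whose probes lie along the whole transcript. The deposited values were 1 signal per transcript cluster and array on a log2 scale. The base of the log was not stated and was taken from the values, which ran from 1.22 to 14.96, below the 16 bits of a scanner. The background correction, probe summary, normalization, software and genome build were not given in the sources used here. The medians and quartiles of the arrays were close but not identical (medians 4.84 to 4.88), so the deposited values had been scaled between arrays or were alike without it. No further normalization was applied in the main analysis. The authors' processing sets the size of every change: a background correction that leaves some background in dim signals would shrink the fold of dim genes.

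The value table held 35399 rows. The platform annotation gave 1 gene symbol for 21789 rows, several for 1621 and none for 11989. Of the rows with 1 symbol, 21698 matched the RefSeq gene table of assembly GRCm38.p6 by gene number, and 0 symbols changed. That table was used for names, gene spans and the order of neighbouring genes, and no coordinates are given because no source named the build of the deposited values. Where a gene had several transcript clusters, which was so for 999 genes, the cluster with the highest mean over the 8 arrays stood for it, so that 19938 genes were tested. Rows with several genes or none were left out of the tests. No dim genes were removed. As a mark of background, the 1015 olfactory receptor genes had a median signal of 3.35 and a 95th percentile of 4.47, and between 67.0% and 68.8% of genes lay above that percentile on each array.

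Groups and replicate numbers were taken from the labels. Each pair of replicates was compared before averaging. The SD of their differences was 0.20 at 0 min, 0.19 at 30 min, 0.23 at 180 min and 0.22 at 300 min on the log2 scale, and no 2 arrays were copies of each other. The labels call the replicates biological but do not say whether they came from separate dissections, so the p-values measure the spread between these arrays. The number of arrays limits the precision of every value, and the model had 4 residual degrees of freedom.

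Genes were tested with limma 3.58.1 in R 4.3.3. A model with a mean for each of the 4 times was fitted to all 8 arrays, with lmFit and eBayes at their default settings (prior degrees of freedom 10.1, prior SD 0.133). Tests were two-sided, with Benjamini-Hochberg adjustment over 19938 genes and a threshold of 0.05. The comparisons were 30, 180 and 300 min each against 0 min, 180 against 30 min, 300 against 180 min, and an F test over all times. Genes called in 2 comparisons against 0 min were counted beside the overlap of independent lists and beside 100 simulations of unchanged groups against the same 0 min arrays. SE is the moderated standard error of a log2 change, and SD is that of the 2 arrays of a time.

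Of 38 gene lists written beforehand, 37 had at least 5 measured genes, and 762 of 839 entries were measured. A list of erythrocyte and blood genes had too few and was not tested. The lists cover classes of activity-regulated genes, synaptic and channel genes, metabolic and stress pathways, and markers of the cell types that a hippocampal culture could hold. Some genes stand on several lists. Lists were tested with camera at its preset correlation of 0.01, with adjustment over the 37 lists for each time. With a correlation estimated for each list, 0 of the 5, 17 and 11 lists called at 30, 180 and 300 min kept an adjusted p under 0.05. A fry test, which asks whether the members of a list move on balance one way, called 3, 8 and 5 of them. Calls adjusted over the list alone are given beside those over all genes.

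The genes named were chosen by a fixed rule: for each comparison against 0 min the 10 largest changes each way among genes that passed and whose arrays did not overlap between the 2 times, for successive times the 5 largest each way, or the 10 smallest p where none passed. Unnamed and predicted loci were left out. A panel of 20 genes and up to 4 members with the smallest p of each list described were added, and a few more members are named where they passed. The chance of 2 arrays lying wholly to one side of 2 others is 33.3%, and it was so for all genes that passed.

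The fit was tested on simulated data for the comparison of 180 with 0 min, in 10 runs over 19938 genes with 100 genes changed by each of 2 sizes. With variances drawn from the fitted prior, 96.5% of changes of 1 on the log2 scale and 18% of changes of 0.5 were recovered, and 5.4% of calls were false. With variances as estimated per gene, these figures were 99.9%, 42.1% and 7.6%. A list of 18 genes shifted by −0.3 was called in 10 of 10 runs, and 0 of the 36 unchanged lists were. The simulated genes varied independently of each other, so these runs do not test false calls of lists whose members vary together.

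The design, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives were quantile normalization, centring on the median, filters on dim genes, testing every row, a replicate block, a mean-variance trend with robust fitting, fitting the compared times alone, a threshold of 1.5-fold, leaving out each array in turn, and for lists an estimated correlation and fry. A filter at the 95th percentile of the olfactory receptor genes, a correction of list tests for gene length, a different 0 min array for each time when shared genes were counted, and robust fitting of every row were added after seeing the data. Figures were drawn from the tabulated values.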

Results

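Gene expression was measured on 8 Affymetrix Mouse Gene ST 1.0 arrays, each hybridised with RNA from cultured hippocampal neurons of ICR mice. ICR is an outbred laboratory strain. The neurons were taken from embryos late in gestation, kept in culture for 10 days and exposed to 50 µM bicuculline. Bicuculline blocks GABA-A receptors, the main inhibitory receptors of the brain, so that network firing rises. RNA was collected at 0, 30, 180 and 300 min, with 2 biological replicates at each time. The values were signals on a log2 scale, and the medians of the 8 arrays lay between 4.84 and 4.88. Replicate arrays correlated at r = 0.988 at 0 min, 0.990 at 30 min, 0.985 at 180 min and 0.988 at 300 min, across all 35399 rows within each pair. The labels named no vehicle-treated culture at the later times, so each change was a difference from the 0 min arrays. With 2 arrays per time, the number of arrays limited the precision of every value.

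The first comparison asked which genes responded within 30 min. The largest change was that of Npas4, a transcription factor induced by neuronal activity, which rose from 5.81 ± 0.20 to 9.69 ± 0.03 (SD, n = 2), a 14.7-fold increase (log2 change 3.88 ± 0.14 SE, limma adjusted p = 2.67e-09). Genes of the AP-1 family rose with it: Fosb 6.67-fold (2.74 ± 0.22), Fos 4.88-fold (2.29 ± 0.15) and Junb 2.54-fold (1.35 ± 0.17). Arc, which encodes a cytoskeleton-associated protein of synaptic plasticity, rose 5.2-fold, and the orphan nuclear receptor gene Nr4a1 rose 4.46-fold. Btg2, an antiproliferative gene, rose 3.6-fold, and the zinc finger genes Egr2, Egr4 and Egr1 rose 2.78-fold, 2.54-fold and 2.49-fold. Gadd45g, a stress-response gene, rose 2.72-fold, and the MAP kinase phosphatase gene Dusp1 rose 2.45-fold.

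In all, 16 genes were higher and 3 were lower at 30 min than at 0 min among 19938 genes (limma, adjusted p under 0.05), and 16 of these 19 changed at least 2-fold. The 3 lower genes were the zinc finger gene Zfp617 (log2 change −1.07 ± 0.16 SE), the amylase gene Amy1 (−1.03 ± 0.14) and the microRNA gene Mir495 (−0.89 ± 0.12), the last at a mean signal of 3.48, below the 95th percentile of the olfactory receptor genes (4.47). Leaving out replicate 2 of the 0 min arrays gave 12 genes, none of them lower. Of the 16 named genes that passed, 11 kept an adjusted p under 0.05 without each of the 8 arrays in turn. Junb lost it without 0 min replicate 2 or 30 min replicate 1, with a highest adjusted p of 0.0713, and Amy1 without the same arrays, with a highest adjusted p of 0.143. Gadd45b, Zfp617 and Mir495 lost it without either 30 min array and without 0 min replicate 2, and Gadd45b also without 0 min replicate 1, with highest adjusted p of 0.303, 0.282 and 0.126. These 5 and Egr4 (adjusted p = 0.113) also lost it when every row was tested, rows without a gene included, which the other 10 did not.

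Of the gene lists fixed beforehand, 4 were higher and 1 was lower at 30 min (camera, adjusted p under 0.05 over 37 lists). Of 29 measured immediate-early transcription factors, 10 rose, 0 fell and 19 did not pass, and 17 rose when adjusted over the list alone (median log2 change 0.53, camera adjusted p = 1.08e-43). Npas4, Fos, Nr4a1 and Btg2 led this list, and the adjusted p was 0.0589 with an estimated correlation. Of 10 activity-regulated survival genes, 5 rose, or 6 when adjusted over the list alone (median 0.83). Npas4, Nr4a1 and Btg2 stood on both lists, and Gadd45g (1.44 ± 0.14 SE) was next. Of 24 rapid effector genes, 5 rose, or 6 when adjusted over the list alone (median 0.23), led by Arc, Gadd45g, Dusp1 and Gadd45b. The survival and effector lists each had an adjusted p of 0.0589 with an estimated correlation. Of 24 feedback inhibitors of MAP kinase signalling, Dusp1 and Dusp6 (0.72 ± 0.12 SE) rose, and 2 did when adjusted over the list alone. The call of that list had an adjusted p of 0.379 with an estimated correlation and of 0.0901 without 0 min replicate 1. The 22 measured genes of RNA polymerase II and mRNA processing were lower as a list (median −0.16), but none passed alone, either over all genes or adjusted over the list alone. The member with the smallest p was the splicing factor gene Srsf5 (−0.49 ± 0.13 SE, limma adjusted p = 0.673), and the list's adjusted p was 0.382 with an estimated correlation and 0.0553 without 30 min replicate 2.

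The second comparison asked which genes differed after 180 min. Fosb was still 5.65-fold above its 0 min signal (log2 change 2.50 ± 0.22 SE), Npas4 3.31-fold (1.73 ± 0.14) and Fos 2.54-fold (1.34 ± 0.15). Lipg, which encodes endothelial lipase, rose from 5.16 ± 0.01 to 7.17 ± 0.15 (SD, n = 2), a 4.04-fold increase (limma adjusted p = 3.64e-06). Bdnf, the gene of brain-derived neurotrophic factor, rose 2.21-fold, and Fezf2, a transcription factor gene of forebrain projection neurons, rose 2.34-fold. Grasp, a postsynaptic scaffold gene, rose 2.13-fold, and Pcsk1, a convertase that cuts prohormones, rose 2.08-fold. Nr4a2, Atf3 and Nr4a1, all transcription factor genes, rose 2.26-fold, 2.11-fold and 2.09-fold.

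In all, 42 genes were higher and 24 were lower at 180 min than at 0 min (limma), and the split was 48 to 17 after quantile normalization and 31 to 30 with each array centred on its median. The largest decrease was that of Zbtb20, a transcriptional repressor gene (log2 change −1.23 ± 0.23 SE, limma adjusted p = 0.042), whose 0 min arrays spread widely (8.11 ± 0.57 SD, n = 2). Trps1, a GATA-type repressor gene, changed by −0.92 ± 0.14, and Kmt2c, a histone H3 lysine methyltransferase gene, by −0.85 ± 0.14. Kctd4 changed by −0.89 ± 0.17, Tgfbr1, a receptor gene for TGF-beta, by −0.82 ± 0.14 and Cabp7, a calcium-binding protein gene, by −0.80 ± 0.14. Raver2 (−0.77), Nbeal1 (−0.76), Tmem131l (−0.74) and Ifi203 (−0.73) also fell, the last at a mean signal of 3.92. A second transcript cluster of Zbtb20, Trps1 and Nbeal1 changed the same way by less, at −0.43, −0.28 and −0.32.

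Each fit without 1 array had fewer residual degrees of freedom than the main fit. Arrays of 30 and 300 min enter the comparison of 180 with 0 min only through the estimate of spread. Lower counts without them therefore do not come from the change itself. The count at 180 min also fell without either 0 min array and without 180 min replicate 1. It was 15 without 0 min replicate 1, 22 without 0 min replicate 2, 23 without either 30 min array, 28 without 180 min replicate 1 and 38 without either 300 min array. Fosb, Lipg, Npas4, Fos, Fezf2, Bdnf and Grasp kept an adjusted p under 0.05 without each array in turn. When every row was tested, rows without a gene included, Lipg alone of these kept it (adjusted p = 0.0119). Npas4 (0.0932), Fezf2 (0.104), Fosb, Bdnf and Grasp (0.113 each) and Fos (0.122) lost it. The other 17 named genes that passed, among them all 10 named genes that fell, lost it without at least 1 array, with highest adjusted p between 0.0614 and 0.268. Zbtb20 and Ifi203, for example, reached 0.268 and 0.199 without 0 min replicate 1, Kctd4 reached 0.226 without 180 min replicate 1 and Nbeal1 reached 0.164 without 0 min replicate 2.

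At 180 min, 9 lists were higher and 8 were lower (camera). Of 28 delayed activity-regulated genes of neurons, 8 rose and 20 did not pass, and 17 rose when adjusted over the list alone (median 0.43, camera adjusted p = 6.8e-18). Its leading members were Gpr3 (1.06 ± 0.12 SE), which encodes a constitutively active receptor, Grasp, Bdnf and Pcsk1, and the adjusted p was 0.148 with an estimated correlation. Of the 29 immediate-early transcription factors, 8 rose, and adjusted over the list alone 12 rose and 1 fell (median 0.25), with an adjusted p of 0.211 with an estimated correlation. Of the 10 survival genes, 4 rose, or 7 when adjusted over the list alone (median 0.60), and of the 24 rapid effectors, 3 rose, namely Per1 (0.91), Rgs2 (0.80) and Homer1 (0.72), or 8 when adjusted over the list alone. Of the 24 feedback inhibitors, Spry2 (0.93), Rgs2 and Dusp4 (0.82) rose, or 6 genes when adjusted over the list alone (median 0.22, and 0.14 without 0 min replicate 1). These 3 lists each had an adjusted p of 0.148 with an estimated correlation.

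On the neuropeptide list of 23 genes, the convertase gene Pcsk1, not itself a neuropeptide gene, and the enkephalin precursor gene Penk (0.83 ± 0.16 SE) rose. Adjusted over the list alone, 7 did (median 0.21, and 0.10 without 180 min replicate 2, adjusted p = 0.212 with an estimated correlation). Of 22 neurotrophin and growth factor genes, Bdnf and Inhba (0.83 ± 0.16 SE), an activin subunit gene, rose (Inhba at 0.54 without 180 min replicate 2 and 1.13 without replicate 1, its call lost without each of the other 7 arrays), or 5 when adjusted over the list alone, with an adjusted p of 0.210 with an estimated correlation. The growth factor list had a median of 0.08. Of 18 core clock genes, Per1, Nfil3 (0.95 ± 0.14 SE) and Per2 (0.68 ± 0.13 SE) rose, or 4 when adjusted over the list alone, with an adjusted p of 0.148 with an estimated correlation. The clock list had a median of 0.10, and 0.005 without 180 min replicate 1. Of 20 NF-kappaB and cytokine genes, none passed over all genes and 5 rose when adjusted over the list alone (median 0.20). Rel (0.53), Icam1 (0.45) and Ptgs2 (0.61) had the smallest p in that list, and its adjusted p was 0.163 with an estimated correlation.

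The lists that were lower at 180 min held no member that passed over all genes. The 24 sodium, calcium and HCN channel genes had a median of −0.25, with Cacna1d at −0.45, Cacna1i at −0.43 and Scn8a at −0.45, and none passed when adjusted over the list alone. The 38 axon guidance and adhesion genes had a median of −0.18, and Dcc, a netrin receptor gene (−0.61 ± 0.14 SE), was the 1 gene lower when adjusted over the list alone. The 18 cholesterol biosynthesis genes had a median of −0.22, with 1 lower when adjusted over the list alone, and Hsd17b7 (−0.50), Mvd (−0.39) and Dhcr7 (−0.33) had the smallest p. These lists had adjusted p of 0.212, 0.245 and 0.148 with an estimated correlation. The other lower lists were RNA polymerase II and mRNA processing (22 genes, median −0.14), glutamate receptors (20, −0.12), voltage-gated potassium channels (29, −0.10), chromatin and transcription machinery (27, −0.13) and glycolysis (19, −0.12). Adjusted over the list alone, these 5 lists held 0, 0, 1, 1 and 1 lower genes, and the glycolysis list also held 1 higher gene. Their adjusted p were 0.245, 0.570, 0.211, 0.686 and 0.686 with an estimated correlation, and quantile normalization ended all 5 calls, with adjusted p between 0.116 and 0.438. Correcting for gene length ended the last 4 calls and took the medians to −0.02 for glutamate receptors, −0.08 for potassium channels, −0.10 for chromatin and −0.09 for glycolysis. Without 180 min replicate 1 the RNA polymerase II list reached 0.209, the potassium channel list 0.0709, the chromatin list 0.558 and the glycolysis list 0.136. Without 0 min replicate 1 the glutamate receptor list reached 0.310, the potassium channel list 0.0853 and the chromatin list 0.495, and the glycolysis list reached 0.801 without 0 min replicate 2 and 0.0619 without 180 min replicate 2. Single arrays moved medians too: without 0 min replicate 1 they were −0.15 for the sodium, calcium and HCN channels, −0.12 for axon guidance and −0.05 for glutamate receptors, and without 0 min replicate 2 that of glycolysis was −0.06. Without 180 min replicate 2 they were −0.24 for the RNA polymerase II list and −0.21 for chromatin.

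**Figure D1:**
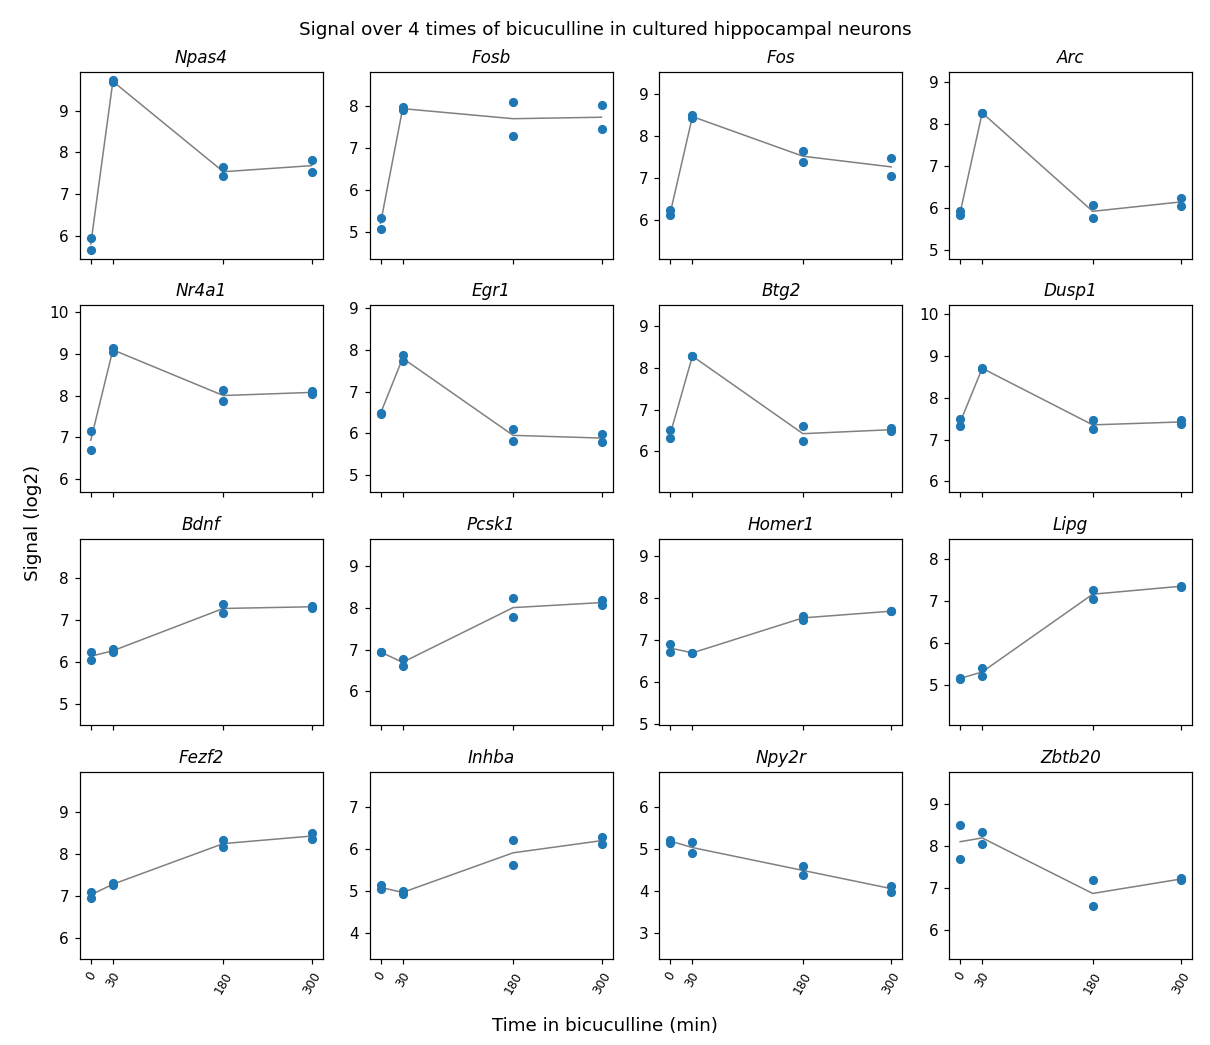
Signal of 16 named genes on a log2 scale (vertical axis, the same span of log2 units in each panel) against minutes in bicuculline (horizontal axis). Points are single arrays, 2 per time, and grey lines join their means. Npas4, Arc, Egr1, Btg2 and Dusp1 were highest at 30 min, while Bdnf, Pcsk1, Homer1, Lipg, Fezf2 and Inhba were higher at 180 and 300 min than at 0 and 30 min.

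The third comparison was of 300 min with 0 min. Fosb was 5.78-fold higher (log2 change 2.53 ± 0.22 SE), Lipg 4.59-fold (2.20 ± 0.13) and Npas4 3.66-fold (1.87 ± 0.14). Fezf2 rose from 7.03 ± 0.10 to 8.44 ± 0.09 (SD, n = 2), a 2.65-fold increase (limma adjusted p = 9.22e-05). Grasp rose 2.45-fold, Gpr3 2.33-fold, Bdnf 2.27-fold, Nr4a2 and Pcsk1 2.26-fold each and Spry2, an inhibitor of growth factor signalling, 2.22-fold. The largest decrease was that of Npy2r, a receptor gene for neuropeptide Y (log2 change −1.13 ± 0.14 SE, limma adjusted p = 0.00167).

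In all, 45 genes were higher and 12 were lower at 300 min (limma). Besides Npy2r, the named genes that fell were B3galt5, a galactosyltransferase gene (−0.79 ± 0.14 SE), Tgfbr1 (−0.77), Trps1 (−0.76), the integrin gene Itga6 (−0.76) and Rps6ka5, a kinase gene of the MAP kinase pathway (−0.75 ± 0.12 SE). The methionine synthase gene Mtr (−0.73), Kmt2c (−0.71), Prox1, a transcription factor gene of dentate granule cells (−0.66), and Tnrc6b, which encodes a partner of Argonaute proteins (−0.65), fell as well. The count was 17 without 0 min replicate 1, 25 without 0 min replicate 2, 33 without either 30 min array and 30 without 300 min replicate 1. Of 25 named genes that passed, 10 kept an adjusted p under 0.05 without each array in turn: Fosb, Lipg, Npas4, Fezf2, Grasp, Gpr3, Bdnf, Pcsk1, Spry2 and Npy2r. Of these, Fosb and Bdnf (adjusted p = 0.116 each), Npy2r (0.187), Pcsk1 and Spry2 (0.219 each) lost it when every row was tested, rows without a gene included. The other 15 of the 25, which included 9 of the 10 named genes that fell, lost it without at least 1 array, with highest adjusted p between 0.0676 for Homer1, without 0 min replicate 2, and 0.347 for Kmt2c, without 0 min replicate 1.

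At 300 min, 8 lists were higher and 3 were lower (camera). Of the 28 delayed genes, 7 rose, and adjusted over the list alone 19 rose and 1 fell (median 0.54, camera adjusted p = 8.71e-22, and adjusted p = 0.186 with an estimated correlation). Grasp, Gpr3, Bdnf and Pcsk1 led this list. Of the 29 immediate-early transcription factors, 9 rose, or 12 when adjusted over the list alone with 1 lower (median 0.20, and 0.39 without 300 min replicate 1, adjusted p = 0.275 with an estimated correlation), led by Npas4, Fosb, Nr4a1 and Fos. Of the 10 survival genes, 4 rose, or 6 when adjusted over the list alone, and of the 24 rapid effectors, Per1 (0.97), Homer1 (0.88), Rgs2 (0.81) and Ptgs2 (0.95), the cyclooxygenase-2 gene, rose, or 9 when adjusted over the list alone. Both lists had an adjusted p of 0.186 with an estimated correlation. On the neuropeptide list, the convertase gene Pcsk1 and Penk (0.93) rose, or 5 when adjusted over the list alone (adjusted p = 0.275 with an estimated correlation). Spry2, Dusp4 (1.02 ± 0.14 SE) and Rgs2 rose among the feedback inhibitors, or 7 when adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). Per1, Nfil3 and Per2 (0.78 ± 0.13 SE) rose among the clock genes, or 5 when adjusted over the list alone (adjusted p = 0.186 with an estimated correlation). The clock list had a median of 0.03, with 11 members positive and 7 negative.

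In fry, the immediate-early transcription factors and the neuropeptides lost their calls at 300 min (adjusted p = 0.0635 each). The NF-kappaB, channel, cholesterol and histone lists lost their calls at 300 min in fry too, and under more of the other alternatives. The other 5 lists called at 300 min kept their calls in fry. Of the NF-kappaB and cytokine genes, Ptgs2 rose, or 2 genes when adjusted over the list alone (list median 0.07, adjusted p = 0.472 with an estimated correlation). The sodium, calcium and HCN channel genes (median −0.13), the cholesterol biosynthesis genes (−0.13, with Insig1 at −0.32 and Mvd at −0.31) and 7 histone genes (−0.16, with H4c4 at −0.40) were lower as lists. None of their members passed, adjusted over the list alone included, and the adjusted p were 0.495, 0.275 and 0.472 with an estimated correlation. Quantile normalization ended these 4 calls, with adjusted p of 0.0690, 0.0810, 0.0810 and 0.0612. Without 0 min replicate 1 the adjusted p were 0.165, 0.497, 0.0931 and 0.117. Without 300 min replicate 1 they were 0.177 for the NF-kappaB list, 0.216 for the cholesterol list and 0.626 for the histone list, and without 300 min replicate 2 they were 0.381 for the channel list and 0.0592 for the NF-kappaB list. The NF-kappaB list also reached 0.0532 without either 30 min array, and the histone list 0.0612 without 0 min replicate 2. The channel median was −0.02 without 0 min replicate 1 and −0.07 without 300 min replicate 2. Without 300 min replicate 1 the medians were −0.07 for cholesterol and −0.08 for histones, and without 300 min replicate 2 they were −0.19, −0.27 and, for NF-kappaB, 0.04.

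**Figure D2:**
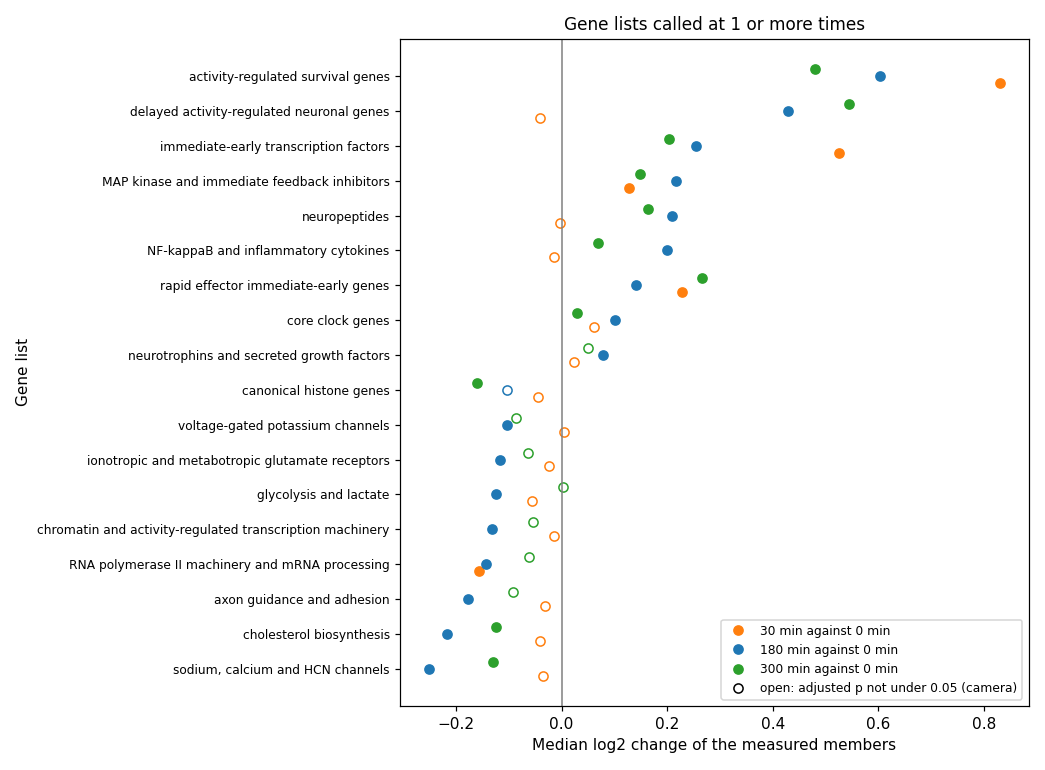
Median log2 change of the measured members (horizontal axis) of the 18 gene lists (vertical axis) that were called at 1 or more times against 0 min. Colours give the time, filled points have a camera adjusted p under 0.05 and open points do not. The delayed neuronal genes were near 0 at 30 min and at 0.43 and 0.54 at 180 and 300 min, while the immediate-early transcription factors were highest at 30 min, at 0.53.

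The other 19 lists were called at no time against 0 min, with medians between −0.12 and 0.08 and a smallest camera adjusted p of 0.0504, that of 23 cytosolic ribosomal protein genes at 300 min. The marker lists of cell types were among them. Their medians at 30, 180 and 300 min were 0.04, −0.04 and 0.02 for excitatory neurons, 0.03, 0.08 and −0.06 for inhibitory neurons and −0.03, 0.02 and −0.12 for astrocytes and radial glia. They were 0.02, 0.04 and −0.08 for the oligodendrocyte lineage, −0.01, 0.05 and −0.09 for microglia and macrophages and 0.05 at each time for endothelial cells and pericytes. For fibroblasts and meninges they were 0, 0.05 and −0.11, and for cell division −0.03, −0.04 and −0.06. Fezf2 and Prox1, which changed in opposite directions at 300 min, were both on the excitatory neuron list. Adjusted over that list alone, Fezf2 and Slc17a6 (0.36) were higher and Prox1 (−0.59) and Zbtb18 (−0.55) lower at 180 min, and 2 were higher and 1 lower at 300 min, so its medians near 0 cover members that went both ways. Over the astrocyte list alone, Sox9 (0.46) and S100b (0.48) were higher at 30 min. The postsynaptic density list had 1 higher member at each time, over all genes and over the list alone, and the interferon list 1 lower at 180 min over the list alone. The smallest camera adjusted p were 0.199 for postsynaptic density scaffolds, 0.104 for GABA receptors and the inhibitory synapse, 0.639 for inward rectifier, leak and calcium-activated potassium channels and 0.425 for synaptic vesicle and release genes. They were 0.143 for oxidative phosphorylation, 0.180 for the unfolded protein response, 0.155 for heat shock, 0.108 for apoptosis and p53 targets, 0.223 for the interferon response and 0.484 for oxidative stress defence.

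Most genes that had risen at 30 min were lower again at 180 min. Of the 16 genes higher at 30 min, 13 were lower at 180 min than at 30 min in the test of that difference, and 4 were still higher than at 0 min at 180 min and 4 at 300 min. Arc fell from 8.27 ± 0.01 at 30 min to 5.92 ± 0.22 at 180 min (SD, n = 2), a 5.09-fold decrease (log2 change −2.35 ± 0.13 SE, limma adjusted p = 9.7e-07). Npas4 fell 4.45-fold over the same interval, Btg2 3.6-fold, Egr1 3.57-fold and Egr2 3.07-fold. The largest increases from 30 to 180 min were those of Lipg (3.63-fold), the microRNA gene Mir377 (2.55-fold), Amy1 (2.5-fold), Pcsk1 (2.47-fold) and the microRNA gene Mir539 (2.18-fold). Amy1 and Mir495, both lower at 30 min than at 0 min, were among the 66 genes higher at 180 min than at 30 min, and 34 genes were lower (limma). The count of 100 fell to 17 without 30 min replicate 1, 26 without 30 min replicate 2 and 60 without 180 min replicate 1. Mir377 lost its call without 30 min replicate 1 (adjusted p = 0.247) or 180 min replicate 1, and Mir539 without either 30 min array (highest adjusted p 0.316) or without 180 min replicate 1, where its log2 change was 0.70 in place of 1.12. Both genes, with Amy1 (adjusted p = 0.0763) and Pcsk1 (0.0901), also lost it when every row was tested, rows without a gene included.

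Between 180 and 300 min no gene passed in limma (0 of 19938, smallest adjusted p = 0.529), and 1141 genes had an unadjusted p under 0.05. The smallest p were those of Svs3b (log2 change −0.75 ± 0.13 SE), Olfr963 (−0.71), Fbln5, an elastic fibre gene (−0.64 ± 0.12 SE), and Olfr566 (−0.75), and 3 of these 4 had a signal below the 95th percentile of the olfactory receptor genes. Gml (−0.64), Olfr47 (0.78), Vmn2r110 (−0.62), Steap4 (−0.63), Hnrnpr (0.74) and Rassf4 (−0.59) followed. The count was 14 without 180 min replicate 2, 1 without 300 min replicate 1 and 2 without 300 min replicate 2.

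**Figure D3:**
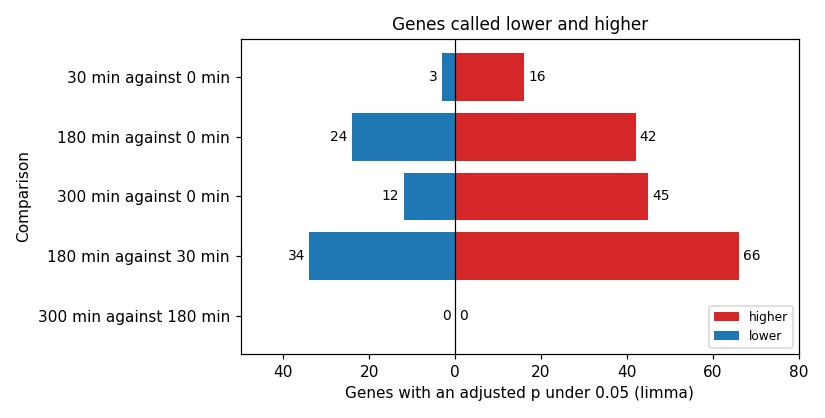
Number of genes with a limma adjusted p under 0.05 (horizontal axis) in each of the 5 comparisons (vertical axis). Red bars to the right count genes that were higher and blue bars to the left genes that were lower at the first time named. The bars run from 3 lower and 16 higher genes at 30 min to 34 lower and 66 higher genes for 180 against 30 min, with 0 for 300 against 180 min.

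Over the whole course, 162 genes differed between any of the 4 times (limma F test, adjusted p under 0.05). That count was 99 without 0 min replicate 1, 49 without 30 min replicate 1, 74 without 30 min replicate 2 and 67 without 300 min replicate 1. Of 71 genes higher at 1 or more times against 0 min, 12 passed at 30 min alone, 14 at 180 min alone and 17 at 300 min alone, and 28 passed at both 180 and 300 min, among them 4 that passed at all 3 times. Fosb, Npas4, Fos and Nr4a1 were these 4. Of 30 genes lower at 1 or more times, 9 passed at both 180 and 300 min. Independent lists would share 0.0948 higher genes and 0.0144 lower genes between 180 and 300 min. Simulated unchanged groups against the same 0 min arrays shared 1 at most, but almost no gene passes in such groups. That simulation therefore does not show what the shared 0 min arrays add to lists of called genes. Across genes, the log2 changes at 180 and 300 min correlated at r = 0.664, against 0.5 in the simulation, with a covariance of 0.0243 against 0.00946. For 30 and 180 min the covariance was 0.0146 (r = 0.454) and for 30 and 300 min it was 0.0101 (r = 0.346), each against 0.00947. Part of this covariance came from the shared 0 min arrays. With a different 0 min array for each time, and so fewer arrays per test, 9 genes were shared between 180 and 300 min either way round, all of them higher, where independent lists would share 0.0107 and 0.0110, and the covariance was 0.0147 and 0.0135. For 30 and 180 min, 3 and 4 genes were shared and the covariance was 0.00593 and 0.00278. For 30 and 300 min, 2 and 4 genes were shared, and the covariance was 0.00210 one way and −0.00224 the other.

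A panel of 20 genes known to respond to neuronal activity had been fixed beforehand, and 11 of them rose at 30 min, 9 at 180 min and 9 at 300 min, with 0 lower at any time. Egr3 had a log2 change of 0.58 ± 0.15 SE at 30 min (limma adjusted p = 0.521), and Egr1, which rose at 30 min, had values of −0.52 at 180 min and −0.59 at 300 min that did not pass. Egr2 had values of −0.14 and 0.00 at these times, Arc 0.03 and 0.26, Dusp1 −0.06 and 0.01, Junb 0.31 and 0.20, Egr3 0.12 and 0.23, Egr4 0.44 and 0.40 and Gadd45b 0.54 and 0.60, and none of these passed. Bdnf (0.13), Homer1 (−0.12), Inhba (−0.12), Nptx2 (−0.15), Pcsk1 (−0.25), Rgs2 (0.17), Scg2 (0.00) and Vgf (0.09) did not pass at 30 min. Homer1 was 1.65-fold higher at 180 min and 1.84-fold at 300 min, Rgs2 1.74-fold and 1.75-fold, and Inhba 1.78-fold and 2.17-fold, all past the threshold with all 8 arrays. Inhba at 180 min kept its call only without 180 min replicate 1 (log2 change 1.13) and was at 0.54 without 180 min replicate 2, with a highest adjusted p of 0.268 without 0 min replicate 1. Homer1 at 180 min lost it without either array of 0 or 30 min and without 180 min replicate 1 (highest adjusted p 0.134). Rgs2 lost it without either 0 min array and without replicate 2 of the later time (highest adjusted p 0.147 at 180 min and 0.127 at 300 min). At 300 min Homer1 lost it without 0 min replicate 2 (0.0676), and Inhba without either 0 min array or 300 min replicate 1 (highest adjusted p 0.118). Nptx2 (0.47 and 0.42), Scg2 (0.58 and 0.48) and Vgf (0.61 and 0.52) did not pass at 180 or 300 min, with adjusted p between 0.0585 and 0.246.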

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

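Both tests of the differences between 30 and 180 min, over the change to 300 min and after quantile normalization, were chosen after the results they measure had been seen.

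Of 45 named genes that passed against 0 min, 31 had a change that differed between 30 and 180 min in limma's test of the difference itself. Of these 31, 19 were lower and 12 higher at 180 min. The log2 changes against 0 min had opposite signs for 11 of them, counting values that did not pass. Across all genes tested, 0 passed in opposite directions at 30 and 180 min. The log2 differences, 180 min minus 30 min, were −2.35 for Arc, −2.16 for Npas4, −1.85 for Btg2, −1.84 for Egr1 and −1.62 for Egr2. They were −1.35 for Dusp1, −1.32 for Zbtb20, −1.09 for Nr4a1, −1.04 for Junb, −0.94 for Fos and −0.90 for Egr4. Differences of −0.78 were found for Raver2 and Gadd45g, −0.74 for Prox1, −0.72 for Trps1, −0.70 for Kmt2c, −0.69 for Cabp7, −0.68 for Tgfbr1 and −0.65 for Tnrc6b. In the other direction they were 0.64 for Rgs2, 0.84 for Homer1, 0.86 for Spry2, 0.95 for Inhba, 0.97 for Fezf2 and Grasp, 1.01 for Gpr3 and Bdnf, 1.11 for Mir495, 1.30 for Pcsk1, 1.32 for Amy1 and 1.86 for Lipg.

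The array of 180 min replicate 1 had the lowest mean correlation with the other arrays (0.984, against 0.987 to 0.988 for the rest). The change from 30 to 300 min uses no 180 min array, and in it 31 of the 31 genes had the same sign and at least 50% of the difference (smallest share 73.3%), which argues against that array alone as the source. After quantile normalization 31 of the 31 genes passed with the same sign and kept at least 93.1% of the difference. Differences in distribution left between the arrays are therefore argued against as the source. The authors' own scaling is not tested by this, because the normalization was applied on top of their processing and cannot undo it. The 30 min arrays are shared by both differences and are not tested by them, and of all 100 genes that passed between 30 and 180 min, 17 did so without 30 min replicate 1, 22 without 30 min replicate 2, 43 without 180 min replicate 1 and 41 without 180 min replicate 2. An early and a late response to the drug, the difference that the design names, remains a hypothesis, because the labels name no culture without drug at the later times.

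Among the 13610 rows without a single gene, which the comparisons did not use, 2 passed at 30 min when every row of the value table was tested together in limma. Both were lower than at 0 min, with log2 changes of −1.28 and −1.21, and neither has a gene in the annotation.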

How the results depend on the processing

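The filter at the 95th percentile of the olfactory receptor genes, the length correction, the split of the 0 min arrays and the robust fit of every row were chosen after seeing the data. Under quantile normalization and median centring, the counts against 0 min of 19, 66 and 57 genes at 30, 180 and 300 min stayed within 1.5 times. So did the count of 100 between 30 and 180 min and the F test's 162. At 180 min, however, 53 of the 66 genes kept their call after quantile normalization and 55 after median centring. The 1.5-fold threshold removed none of these genes, since each had already changed by more, and so could not test the calls. A filter at the 30th percentile of mean signal gave 91 genes at 300 min, of which 57 were shared with the 57. A filter at the median gave 101 at 180 min and 97 at 300 min, and the olfactory receptor filter 101 and 98, with fewer genes tested. A mean-variance trend with robust fitting gave 108, 91 and 156 genes at 180 min, at 300 min and from 30 to 180 min, and 255 in the F test. Fitting the compared times alone, with fewer arrays, gave 19 at 180 min and 55 from 30 to 180 min. Testing every row of the value table, rows without a gene included, gave 1 at 180 min, 5 at 300 min, 9 from 30 to 180 min and 13 in the F test. With robust fitting of every row there were 3, 8 and 19 at 180 min, at 300 min and from 30 to 180 min. Rows without a single gene vary more (median SD 0.191 against 0.127), and with them the prior degrees of freedom fell from 10.1 to 3.72. Except where fewer genes, fewer arrays or noisier rows show it, the cause was not tested.

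Without each array in turn the counts ran from 12 to 21 at 30 min, 15 to 68 at 180 min, 17 to 61 at 300 min, 17 to 93 from 30 to 180 min, 0 to 14 from 180 to 300 min and 49 to 171 in the F test, and the lists called from 4 to 6, 13 to 17 and 10 to 13. A time left with 1 array was assumed to vary like the others. Each of these fits had fewer residual degrees of freedom, so a call can be lost through lower precision alone. Lists called fell from 5, 17 and 11 to 0, 0 and 0 with an estimated correlation and to 3, 8 and 5 with fry. Fry ended the 30 min calls of feedback inhibitors (adjusted p = 0.113) and RNA polymerase II (0.287). At 180 min it ended those of neurotrophins and neuropeptides (0.0527 each), sodium, calcium and HCN channels (0.0623) and axon guidance (0.0889). The RNA polymerase II, glutamate receptor, potassium channel, chromatin and glycolysis calls at 180 min ended as well. At 300 min, 7 lists were called after quantile normalization and 7 with the median filter. After correction for gene length, 14 and 10 lists were called at 180 and 300 min. The correction ended the calls of glutamate receptors (median −0.12 before and −0.02 after, adjusted p = 0.325), potassium channels (−0.10 and −0.08, 0.159), chromatin (−0.13 and −0.10, 0.279) and glycolysis (−0.12 and −0.09, 0.0501) at 180 min, and those of sodium, calcium and HCN channels (−0.13 and −0.09, 0.143) and NF-kappaB genes (0.07 and 0.05, 0.104) at 300 min.

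The replicate numbers did not pair the arrays (correlations of deviations from −0.094 to 0.092). A replicate block gave 19, 53, 49, 87 and 0 genes in the 5 comparisons, 157 in the F test, 5, 17 and 12 lists, and overlaps of 4, 4 and 28 genes in place of 4, 4 and 37. With a different 0 min array for each time, and so fewer arrays, the overlaps were 3 or 4, 2 or 4, and 9. Of 1195 alternative values for 75 called results of named genes, 945 kept direction and call, 250 lost the call and 0 reversed. Testing every row, with the noisier rows without a gene included, ended 53 of these 75 calls. Of 496 values for 31 results that did not pass, 6 passed: Scg2 at 180 min after quantile normalization, with both filters and with the trend and robust fitting (adjusted p from 0.0203 to 0.0394), Vgf at 180 min with the last (0.0327), and Gadd45b at 300 min without 300 min replicate 1 (0.045).

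The values that changed sign belonged to genes that had not passed. After quantile normalization Scg2 was at 0.016 at 30 min and Dusp1 at 0.002 at 180 min. With median centring Arc was at −0.006 at 180 min and Dusp1 at −0.014 at 300 min. Without each array in turn, the values ran from −0.036 to 0.029 for Scg2 and from −0.064 to 0.25 for Vgf at 30 min. At 180 min they ran from −0.125 to 0.191 for Arc, −0.175 to 0.05 for Dusp1 and −0.306 to 0.02 for Egr2, and at 300 min from −0.071 to 0.09 for Dusp1. The cause was not tested. Dim signals limit what can be called: 1, 7 and 1 of the genes called at 30, 180 and 300 min lay below the olfactory receptor percentile. A planned conversion from a linear scale was not run, since the values were on a log2 scale.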

Other observations

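The tests of small noncoding RNAs in general and of nuclear RNA were chosen after the values they measure had been seen. The genes of the next 2 paragraphs, and the interval between Dlk1 and Dio3, were picked after values of their genes had been seen.

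Some genes outside the rule for named genes were higher at 180 min than at 30 min. Malat1, an abundant nuclear RNA, was 2-fold higher (log2 change 1.00 ± 0.17 SE, limma adjusted p = 0.0143), and the long noncoding RNAs Meg3 1.95-fold (0.97 ± 0.17), Rian 2.02-fold (1.01 ± 0.15), Snhg11 2.09-fold (1.06 ± 0.20) and Firre 1.69-fold (0.76 ± 0.15). Clk4, Luc7l3, Ccnl2, Leng8, Paxbp1, Taf1d and Wsb1 were 1.75-fold, 1.66-fold, 1.56-fold, 1.89-fold, 1.84-fold, 1.62-fold and 1.79-fold higher. These 12 do not stand for a class: the noncoding RNAs Rmrp (−0.90), Rpph1 (−0.74), Tug1 (−0.30) and Airn (−0.08) had lower values at 180 min. None of the 12 passed at 30 or 180 min against 0 min. All 12 lost their call without 30 min replicate 1, and the highest adjusted p without 1 array ran from 0.0778 for Paxbp1, without 30 min replicate 2, to 0.519 for Firre, without 30 min replicate 1. Clk1 rose 2.1-fold at 300 min (adjusted p = 0.0185), a call lost without either array of 0 or 300 min (highest adjusted p 0.145).

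Mir212, a microRNA gene, rose 1.88-fold at 30 min (log2 change 0.91 ± 0.15 SE, limma adjusted p = 0.0285), with values of 0.74 and 0.67 at 180 and 300 min that did not pass. The call at 30 min was lost without either 0 min array, 30 min replicate 2 or either 300 min array (highest adjusted p 0.353). Mir568, which lies next to Zbtb20 in the RefSeq table, fell with it from 30 to 180 min (−0.93 ± 0.18 SE against −1.32 ± 0.23 SE, both past the threshold), but without 30 min replicate 1 the adjusted p were 0.463 and 0.301. Rnpc3, a neighbour of Amy1, had values of −0.77 at 30 min against 0 min and 0.70 from 30 to 180 min that did not pass, beside −1.03 and 1.32 for Amy1.

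Meg3, Rian and Mir495 lie between Dlk1 and Dio3, an imprinted interval, and 45 noncoding genes of that interval were measured (40 microRNA genes, 3 snoRNA genes and 2 long noncoding RNAs). Of these 45, 40 had a negative log2 change at 30 min against 0 min (median −0.28), of which 1 passed, and 41 a positive one from 30 to 180 min (median 0.46, and 0.30 without 180 min replicate 1), of which 6 passed, and at 30 min the set had p = 0.0605 in camera with an estimated correlation and p = 0.0948 in fry, on members picked as said above. A single array apart from the rest is argued against, since the median at 30 min was −0.20 or lower without each of the 8 arrays. The 308 microRNA and snoRNA genes elsewhere had a median of 0.02. They were not filtered on signal, and rows near background can hide a fall. That median therefore cannot decide whether expressed small RNAs shifted in general. Dim signals alone are argued against as well, since the 22 members above the 95th percentile of the olfactory receptor genes had a median of −0.19 (bootstrap 95% interval −0.46 to −0.12, over members that may share host transcripts). A lower yield of nuclear RNA at 30 min cannot be told apart: 4 nuclear long noncoding RNAs from other loci had a median of −0.33, but with Malat1 at −0.75, Firre at −0.65, Tug1 at −0.01 and Airn at 0.16 they are too few and too spread, and a transient loss of the interval's transcripts in stimulated neurons stays open as well.

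Long genes were lower at 180 min than at 0 min: over 18565 protein-coding genes, the Spearman correlation of gene length with the log2 change was −0.26 at 180 min, −0.17 at 300 min and −0.15 at 30 min, across genes that are not independent replicates. Genes over 100 kb had a median of −0.09 at 180 min and genes under 10 kb a median of 0.05, and correcting for length ended the calls of 4 lower lists at 180 min: the median of glutamate receptors went from −0.12 to −0.02, while those of the other 3 stayed between −0.10 and −0.08. The array of 180 min replicate 1 is argued against as the source, since the correlation without it was −0.20, and so are low signals, since the correlation was −0.29 in the brightest 25% of genes and −0.07 in the dimmest 25%. Length trends that differ from array to array regardless of time are argued against too, for 180 against 0 min only. That slope was 5.04 times the SD of slopes that the replicate differences give, against a bound of 2.78, while at 300 min it was 2.80 times. Both ratios share the 0 min arrays. With an SD of 0.016, the slope per 10-fold length was −0.078 for 180 against 0 min and −0.043 for 180 against 30 min. It was −0.035 for 30 against 0 min and 0.035 for 300 against 180 min, and no ratio was taken for these last 3 comparisons. A change in the handling or integrity of the RNA between times, or slower renewal of long transcripts in stimulated neurons, may each give such a trend, and neither was tested.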
